A study of Mus musculus with 40 samples.

How the data were processed

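The series measured RNA in 40 libraries of sorted mouse bone marrow B-lineage cells. Per the labels' protocols, lethally irradiated CD45.1 hosts received marrow from wild-type (WT) donors or from donors homozygous for a proline to alanine change at residue 198 (P198A) of the zinc transporter ZIP7, encoded by Slc39a7. Fractions FrB, FrC, FrD and FrE of the Hardy scheme were sorted from the donor cells after 8 weeks, 100 cells to a library. The labels describe gates for FrB (B220+ CD43+ CD24+ BP1-, with no IgM or IgD gate named), FrD (B220+ CD43- IgM- IgD-) and FrE (B220+ CD43- IgM+ IgD-), and the gate of FrC is not given in the sources used here. Libraries were made with Smart-seq2 and a Nextera XT dual-index kit, with ERCC spike-in RNA in the lysis buffer, per the labels' protocols. The titles abbreviate the mutant group as KO, but the allele is a missense knock-in, so the level of Slc39a7 RNA does not check the genotype. Titles also give a mouse number (WT mice 1, 2, 3, 6 and 7, mutant mice 4, 5, 8, 9 and 10) and both index names. Libraries with the same number come from the same animal, which is where the pairing across fractions comes from. Genotypes were compared without pairing.

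The deposited table holds raw counts per gene that the authors made from their reads. Per the submitters' processing notes, the tools named were HISAT2 2.1.0, featureCounts 1.4.6 of the Subread package and DESeq2, with genome build mm10. The annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes cannot be told apart by these counts, and near-identical paralogs such as the Bcl2a1 genes are uncertain. The table has 22050 rows, 92 of them spike-in transcripts and 21958 of them genes, of which 2904 had no count in any library. Gene identifiers were looked up in GENCODE M21, which uses the same build. This gave a match for 21728, 21383 of them protein coding, and the 230 unmatched held 0.0325% of the counts. Mitochondrial genes and immunoglobulin V, D and J segments are not analysed here. Coordinates are those of that annotation, counted from 1.

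Endogenous totals ran from 42111 to 43372070 counts per library, with a median of 16474388 and a second lowest total of 1723215. Counts come from amplified reads without molecular identifiers, so bounds based on counts cover counting error only. A group whose libraries all had a count of 0 was given a floor of 3 counts over the group. No libraries were identical, and the highest correlation between any pair was 0.928. Same-mouse libraries of consecutive fractions deviated together by a median correlation of only -0.01 to 0.05 over the 6 steps tested, so the pairing rests on the animal and not on this check.

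Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust fit, TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15), on endogenous genes only, with two-sided p-values, and called at a Benjamini-Hochberg adjusted p under 0.05. Each genotype effect in a fraction was fitted on its 10 libraries. The effect over fractions used counts summed to 1 column per mouse. Steps between consecutive WT fractions were fitted on the 20 WT libraries without a block, and the differences in step between genotypes on all 40. Errors given after ± are SD for levels in CPM and SE for fitted log2 fold changes. The log2 ratio of endogenous to ERCC counts, total counts, genes detected and the share of the 50 highest genes were compared by exact two-sided permutation tests (252 arrangements, smallest possible p 0.00794), adjusted over the fractions or steps of a measure. Each of these choices, the gene lists and the rule for named genes were fixed before the data were examined.

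Gene lists were tested with camera of limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. P-values were adjusted over the lists of a comparison. The lists covered zinc transporters, metallothioneins and MTF1 targets, the unfolded protein response, the integrated stress response, the pre-BCR and BCR complex, V(D)J recombination, pro-B and progenitor genes, immature and mature B genes, BCR signalling, immediate early genes, IL-7 and STAT5 targets, FOXO targets, pre-B transcription factors, G1/S and DNA replication, G2/M and mitosis, p53 targets, apoptosis regulators, protein tyrosine phosphatases, oxidative stress, oxidative phosphorylation, glycolysis, cholesterol synthesis, cytosolic ribosomal proteins, interferon response, heat shock and cell handling, Slc39a7 and its chromosomal neighbours, and markers of T, NK, plasmacytoid dendritic, granulocyte and monocyte, erythroid, megakaryocyte, basophil, mast and eosinophil, plasma and stromal cells. A list of sex-linked genes, with 4 members in the table, had too few tested members and gave no result. Named genes are those called in a genotype effect, or the 10 of lowest p in each direction where more than 20 were called, or the 5 of lowest p where none was. In WT steps they are the 10 of lowest p in each direction, and in differences between genotypes up to 10 called genes. Gm and Rik models, pseudogenes, immunoglobulin segments and ribosomal protein genes were left out of these ranks. Up to 4 members of each list per comparison, and Slc39a7 throughout, were added.

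Alternatives planned for each comparison were DESeq2 size factors, no filter, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, scaling to ERCC totals, the set of second index as a covariate, a joint fit of all 40 libraries, the mouse as a block or random effect, and leaving out each mouse. Fits without 10 libraries of low complexity were added after the data were seen. These are the libraries in which over 15% of detected genes had 1 to 9 counts. The lowest of them had 16.4% and the highest of the other 30 had 14.7%. In mutant FrB 1 library is then left, which is assumed to vary like the others. Tables and plots were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

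The gene test was checked on counts simulated from the real means and library sizes. Of genes changed 4-fold, edgeR recovered 8.3% for the genotype effect in FrB, 3.1% in FrC, 15.2% in FrD, 20.8% in FrE and 67.0% over fractions. It recovered 21.4%, 21.4% and 27.8% for the WT steps from FrB to FrC, FrC to FrD and FrD to FrE, and 3.1%, 2.1% and 2.0% for the differences in these steps. Of genes changed 16-fold it recovered 53.3%, 51.6%, 61.1%, 68.8% and 87.5% for the genotype effects in the same order, 58.8%, 66.3% and 47.4% for the steps, and 36.4%, 28.3% and 31.6% for their differences. False calls made up 0.0% to 8.3% of the edgeR calls. The share was 20.4% to 35.4% for the DESeq2 Wald test in genotype effects and steps, and 66.7% to 71.7% in differences of steps. Apart from the changed genes, all simulated libraries shared 1 mean and 1 spread per gene. Low-complexity libraries gathered in 1 genotype were not simulated, so these shares do not carry over to the real FrB calls. In simulated FrE libraries with 1 list raised 4-fold, camera gave that list an adjusted p of 1.71e-11 and called 0 of 28 other lists.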

Results

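RNA was counted in 40 libraries of 100 sorted donor cells each, from 10 bone marrow chimeric mice. Of these mice 5 carried WT marrow and 5 carried marrow homozygous for P198A in ZIP7, a zinc transporter of the endoplasmic reticulum and Golgi membranes. Each mouse gave 1 library of FrB (pro-B cells), FrC (whose gate and stage are not given in the sources used here), FrD (late pre-B cells) and FrE (immature B cells), so that each of the 8 groups held 5 libraries. Median totals of endogenous counts were 15960698, 15156206, 20432166 and 18270663 in WT FrB, FrC, FrD and FrE. In the mutants they were 9440875, 9704316, 23574091 and 19511301. Totals of single libraries ran from 42111 in FrE of mutant mouse 9 to 43372070 in FrD of the same mouse. Bounds against groups without counts cover counting error only.

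The labels divide the study by genotype and by stage, and the first question is whether the mutation goes with a difference in RNA content. The log2 ratio of endogenous to spike-in counts differed by 0.68 in FrB (mutant 10.69 ± 0.96, WT 10 ± 0.87, SD, n = 5 each, exact permutation p = 0.254, adjusted 0.603). In FrC it was 11.17 ± 2.20 in mutants and 10.64 ± 0.89 in WT (SD, n = 5 each, exact permutation p = 0.643, adjusted 0.643), a difference of 0.53 that was -0.12 without mutant mouse 9. The ratio was 8.81 ± 0.34 against 8.41 ± 1.01 in FrD and 8.42 ± 0.69 against 8.80 ± 0.40 in FrE (SD, n = 5 each, exact permutation p = 0.452 and 0.31, both adjusted to 0.603). The FrD difference of 0.40 was 0.04 without mouse 7 and -0.02 without the 3 most abundant spike-ins. Ratios also went with mouse number, in FrD from 8.8 to 9.5 in mice 1 to 5 and from 7.0 to 8.6 in mice 6 to 10. Within these sets FrB mutants lay above WT (11.7 and 11.3 against 10.6 to 10.8, and 9.2 to 10.8 against 9.0 and 9.1). In FrC mutant mice 8 and 10 (8.6 and 9.3) lay below WT mice 6 and 7 (both 9.7), and mutant mouse 9 (13.8) lay above them. Mutant mice 4 and 5 stood at 11.4 and 12.8 there, against 11.1 to 11.6 in WT mice 1, 2 and 3. The tests took no account of these sets, so they do not exclude a genotype difference. In WT cells the same ratio fell by 2.23, or 4.7-fold, from FrC to FrD (n = 5 each, exact permutation p = 0.00794, the smallest possible, adjusted 0.0238), and it was lower in FrD in 5 of 5 mice. The tests of WT steps treat libraries of 1 mouse as independent, and a paired exact test of that fall cannot go below p = 0.0625. Without the 3 most abundant spike-ins that fall was 1.82 and did not pass (adjusted exact permutation p = 0.143). From FrB to FrC it differed by 0.64 and from FrD to FrE by 0.38, or -0.02 without mouse 7 (n = 5 each, exact permutation p = 0.278 and 0.46, adjusted 0.417 and 0.46). The ratio was higher in FrC than in FrB of the same mouse in 5 of 5 mice, for which a paired exact test cannot go below p = 0.0625, and higher in FrE than in FrD in 3 of 5.

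**Figure D1:**
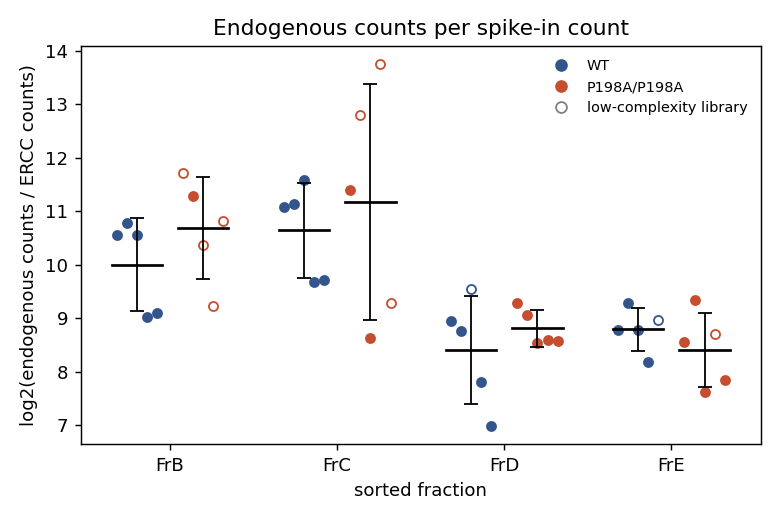
Log2 ratio of endogenous to ERCC counts per library (y axis) in each sorted fraction (x axis), with WT and P198A/P198A libraries in separate colours, open points for low-complexity libraries and bars for the group mean and SD (n = 5). The WT mean falls by 2.23 from FrC to FrD (by 1.82, which does not pass, without the 3 most abundant spike-ins), and no genotype difference passes the exact permutation test.

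Libraries of low complexity were unevenly spread over the groups. In 10 libraries over 15% of the detected genes had only 1 to 9 counts, and these 10 stood apart from the other 30 on the first principal component, which held 14.9% of the variance. They were FrB of mutant mice 4, 8, 9 and 10, FrC of mutant mice 5, 9 and 10, FrE of mutant mouse 9, FrD of WT mouse 3 and FrE of WT mouse 7. That is 8 of 20 mutant and 2 of 20 WT libraries (Fisher's exact p = 0.0648), with 4 of 5 against 0 of 5 in FrB (Fisher's exact p = 0.0476) and 3 of 5 against 0 of 5 in FrC (Fisher's exact p = 0.167). The test over 20 libraries a genotype treats libraries of 1 mouse as independent, though mutant mouse 9 is on the list in FrB, FrC and FrE. Mutants had fewer detected genes in FrB (11124 ± 602 against 11831 ± 135) and in FrC (10987 ± 491 against 11568 ± 94) and more in FrD (11252 ± 278 against 10705 ± 288), each with an adjusted exact permutation p of 0.0423 (SD, n = 5 each). In FrE the numbers were 10152 ± 1576 and 10833 ± 174 (SD, n = 5 each, adjusted exact permutation p = 0.579).

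Slc39a7 encodes ZIP7 (ENSMUSG00000024327, chromosome 17, 34028269 to 34031682, minus strand, GRCm38). Its RNA was higher in mutant FrB, at 153.2 ± 91.6 against 39.6 ± 9.0 CPM (SD, n = 5 each), a log2 fold change of 1.93 ± 0.54 (SE, adjusted p = 0.0426). It was -0.15 without the low-complexity libraries. In FrC, FrD and FrE mutant levels were 89.1 ± 70.4, 57.9 ± 37.6 and 52.5 ± 29.0 CPM, and WT levels were 33.6 ± 17.5, 80.5 ± 110.4 and 123.0 ± 176.0 CPM (SD, n = 5 each). Log2 fold changes there were 1.47 ± 0.77, -0.44 ± 0.78 and -1.32 ± 0.94 (SE), with adjusted p of 0.517, 0.998 and 0.999, and the value over all fractions was 0.72 ± 0.33 (adjusted p = 0.295). The high means of WT FrD and FrE rest on mouse 3 in FrD (277.3 CPM) and mouse 7 in FrE (428.4 CPM), both low-complexity libraries. The 15 tested members of the list of Slc39a7 and its chromosomal neighbours stood at a median of 0.53 in mutant FrC (camera adjusted p = 0.0116, and adjusted p = 0.337 with an estimated correlation), and at 0.17 without low-complexity libraries. Other zinc transporter genes, 16 of them tested in FrB, did not pass as a list in any fraction (camera adjusted p = 0.698, 0.952, 0.879 and 0.217 in FrB, FrC, FrD and FrE). Metallothioneins and MTF1 targets, which zinc induces, did not pass either (0.666, 0.371, 0.929 and 0.887).

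In FrB, the pro-B stage, 596 genes were higher and 182 lower in mutants out of 10562 tested. Genes of immature and mature B cells were lower: all 26 tested members lay below 0, with a median of -2.32, 11 of them called over all genes and 13 when adjusted over the list alone (camera adjusted p = 1.24e-13, and 0.00506 with an estimated correlation). Cd74, the invariant chain of MHC class II (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), fell from 4353.0 ± 1077.5 to 234.5 ± 79.3 CPM (SD, n = 5 each), a log2 fold change of -4.23 ± 0.30 (SE, adjusted p = 3.49e-06). Fcmr, the receptor for IgM Fc, fell by 3.98 ± 0.62 (SE, adjusted p = 0.00412) and Tnfrsf13c, the BAFF receptor, by 2.93 ± 0.49 (SE, adjusted p = 0.00442). The signalling chains of the B cell receptor were also lower, Cd79a by 2.22 and Cd79b by 1.47. Other genes among the lowest p were Ms4a4c (-7.73), Fcrl1 (-6.59), Cd2 (-5.42), Zbtb32 (-8.31), Zfp51 (-6.84), Acadvl (-8.04) and Ctss (-2.81). Fah, the last enzyme of tyrosine breakdown, had 2 counts over the 5 mutant libraries and 2449 over the 5 WT libraries.

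Among the genes higher in mutant FrB, Lars2, the mitochondrial leucyl-tRNA synthetase (ENSMUSG00000035202, chromosome 9, 123366927 to 123462666), had the lowest p. It rose from 735.6 ± 287.9 to 38689.3 ± 23860.6 CPM (SD, n = 5 each), a log2 fold change of 5.71 ± 0.60 (SE, adjusted p = 0.00046). Lars2 also stood at 30607.3 CPM in FrD of WT mouse 3 and at 37178.7 CPM in FrE of WT mouse 7, both low-complexity libraries. Csnk1g2 (3.89), Scap (3.85), Sox4 (3.77), Abcf1 (2.99), Cplx2 (2.83), Grk2 (2.75), Rcc2 (2.56), Baz1b (2.56) and Incenp (2.54) followed, each with an adjusted p of 0.00396. Of 17 pro-B and progenitor genes 5 rose, among them Sox4, Spn (3.22), Ebf1 (1.64) and the surrogate light chain gene Vpreb1 (1.18), and 8 when adjusted over the list alone (median 0.92, camera adjusted p = 0.00467, and adjusted p = 0.344 with an estimated correlation). Of 21 pre-B transcription factors 4 rose, Bach2 by 1.92, and 8 when adjusted over the list alone (median 0.89, camera adjusted p = 0.0024, and adjusted p = 0.222 with an estimated correlation). Rag1, a V(D)J recombinase gene, rose by 2.21 and Atf4, the effector of the integrated stress response, by 1.46. Cytosolic ribosomal protein genes rose as a list, with 42 of 86 called, 52 adjusted over the list alone and a median of 1.35 (camera adjusted p = 2.94e-26, and adjusted p = 0.237 with an estimated correlation). For oxidative phosphorylation the numbers were 12 of 45 called, 17 over the list alone and a median of 0.40 (camera adjusted p = 0.000183, and adjusted p = 0.344 with an estimated correlation).

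Markers of other cells moved in FrB as well. Granulocyte and monocyte genes stood at a median of 3.39, with Mpo (7.92), Mmp8 (7.25) and Mmp9 (6.55) called of 20 tested and 8 adjusted over the list alone (camera adjusted p = 0.000216, and adjusted p = 0.572 with an estimated correlation). Mpo, the myeloperoxidase of neutrophil granules, was at 510.0 ± 557.7 CPM in mutants and 2.1 ± 2.3 in WT (SD, n = 5 each). Of 8 plasma cell genes 2 fell and 5 when adjusted over the list alone, at a median of -2.15 (camera adjusted p = 0.00205, and adjusted p = 0.509 with an estimated correlation). Jchain, the joining chain of secreted immunoglobulin, was at 4841.2 ± 4876.3 CPM in mutants and 25476.1 ± 13445.3 in WT (SD, n = 5 each, adjusted p = 0.0961). Of 30 genes of the unfolded protein response 6 fell, among them Dnajb9 (-3.30), Xbp1 (-2.61), Creld2 (-1.70) and Pdia3 (-1.71), while the list as a whole did not pass (median -0.26, camera adjusted p = 0.0719). Interferon response genes stood at a median of -0.77 with 0 of 25 called (camera adjusted p = 0.0118, and adjusted p = 0.344 with an estimated correlation). Erythroid genes stood at -1.33 with 1 of 12 called, Car1 (camera adjusted p = 0.0295, and adjusted p = 0.725 with an estimated correlation).

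The FrB calls depended on the libraries of low complexity. Without them 16 genes were higher and 136 lower, 77 of these 152 being called with all libraries too, and the single mutant library left was assumed to vary like the others. Of the higher genes named, Lars2 (2.33), Csnk1g2 (1.84), Baz1b (1.63) and Bach2 (1.52) were still called, while Sox4 (1.33), Ebf1 (0.43), Rag1 (0.30), Atf4 (0.09), Vpreb1 (0.09) and Mpo (-1.97) were not. The lists of pro-B, pre-B factor, granulocyte and erythroid genes then had medians of 0.07, 0.27, -1.45 and -0.25 and adjusted p of 0.546, 0.284, 0.892 and 0.908. Ribosomal protein genes stood at 0.62, interferon response genes at -1.53 and immature and mature B genes at -2.84. Total calls were 264, 273, 344, 399 and 330 without WT mouse 1, 2, 3, 6 or 7 and 1937 without mutant mouse 5, while scaling to ERCC totals gave 124 higher and 24 lower, the second-index covariate 268 and 130, and DESeq2 1277 and 472.

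In FrC edgeR called 0 genes of 10299, with 1168 at an unadjusted p under 0.05. DESeq2 called 174 higher and voom 3 lower, while ERCC scaling gave 222 higher and 3 lower and the joint fit 618 and 9. The 5 genes of lowest p did not pass (adjusted p = 0.271 each). Rab12 stood at 4.18 ± 0.96 (log2, SE), Tfeb at 4.38, Ccnjl at 11.28 and Usp36 at 3.01. Without the low-complexity libraries these were 0.60, 0.05, 3.44 and 0.82 in the same order. Shb had no counts in mutants and 164 over the 5 WT libraries, which is at least 53.1-fold lower by a bound that covers counting error only. Gene lists did move. Immature and mature B genes were lower, with 23 of 26 below 0, 1 called when adjusted over the list alone and a median of -1.04 (camera adjusted p = 4.72e-11, and adjusted p = 0.189 with an estimated correlation). H2-Eb1, an MHC class II chain, stood at -2.14. Ribosomal protein genes were higher, 42 of 86 when adjusted over the list alone, with a median of 1.98 (camera adjusted p = 1.14e-29, and adjusted p = 0.189 with an estimated correlation). Without the low-complexity libraries that median was 0.18 (camera adjusted p = 5.62e-09, and adjusted p = 0.736 with an estimated correlation), while that of immature and mature B genes was -1.08.

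Pro-B and progenitor genes in mutant FrC stood at a median of 0.77, 16 of 17 above 0 and 2 called when adjusted over the list alone (camera adjusted p = 0.000914, and adjusted p = 0.189 with an estimated correlation). Pre-B transcription factors had a median of 0.43 (camera adjusted p = 0.0151, and adjusted p = 0.714 with an estimated correlation), and oxidative phosphorylation genes 0.37 (camera adjusted p = 0.00181, and adjusted p = 0.148 with an estimated correlation). The unfolded protein response was higher at a median of 0.17 (camera adjusted p = 0.00256, and adjusted p = 0.29 with an estimated correlation). The integrated stress response was higher at 0.47, 12 of 15 above 0 and 1 when adjusted over the list alone (camera adjusted p = 0.0474, and adjusted p = 0.189 with an estimated correlation). Ddit3, which encodes CHOP, stood at 2.33 ± 0.76 and Slc7a5, an amino acid transporter, at 3.97 ± 1.13 (SE, both adjusted p = 0.271), and at 1.61 and 0.59 without the low-complexity libraries. Granulocyte and monocyte genes stood at a median of 1.94 (camera adjusted p = 0.952), and at -3.21 with 15 of 15 below 0 without the low-complexity libraries (camera adjusted p = 3.73e-05, and adjusted p = 0.5 with an estimated correlation). Erythroid genes had a median of 4.84 and a mean of 2.04, opposite in sign to the list's test, which ranked them lower (camera adjusted p = 2.36e-05, and adjusted p = 0.294 with an estimated correlation), and their median was -7.55 without those libraries. The lists of pro-B genes, pre-B factors and oxidative phosphorylation then had medians of 0.02, -0.05 and 0.05 and adjusted p of 0.205, 0.424 and 0.2, and the neighbours of Slc39a7 an adjusted p of 0.282.

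**Figure D2:**
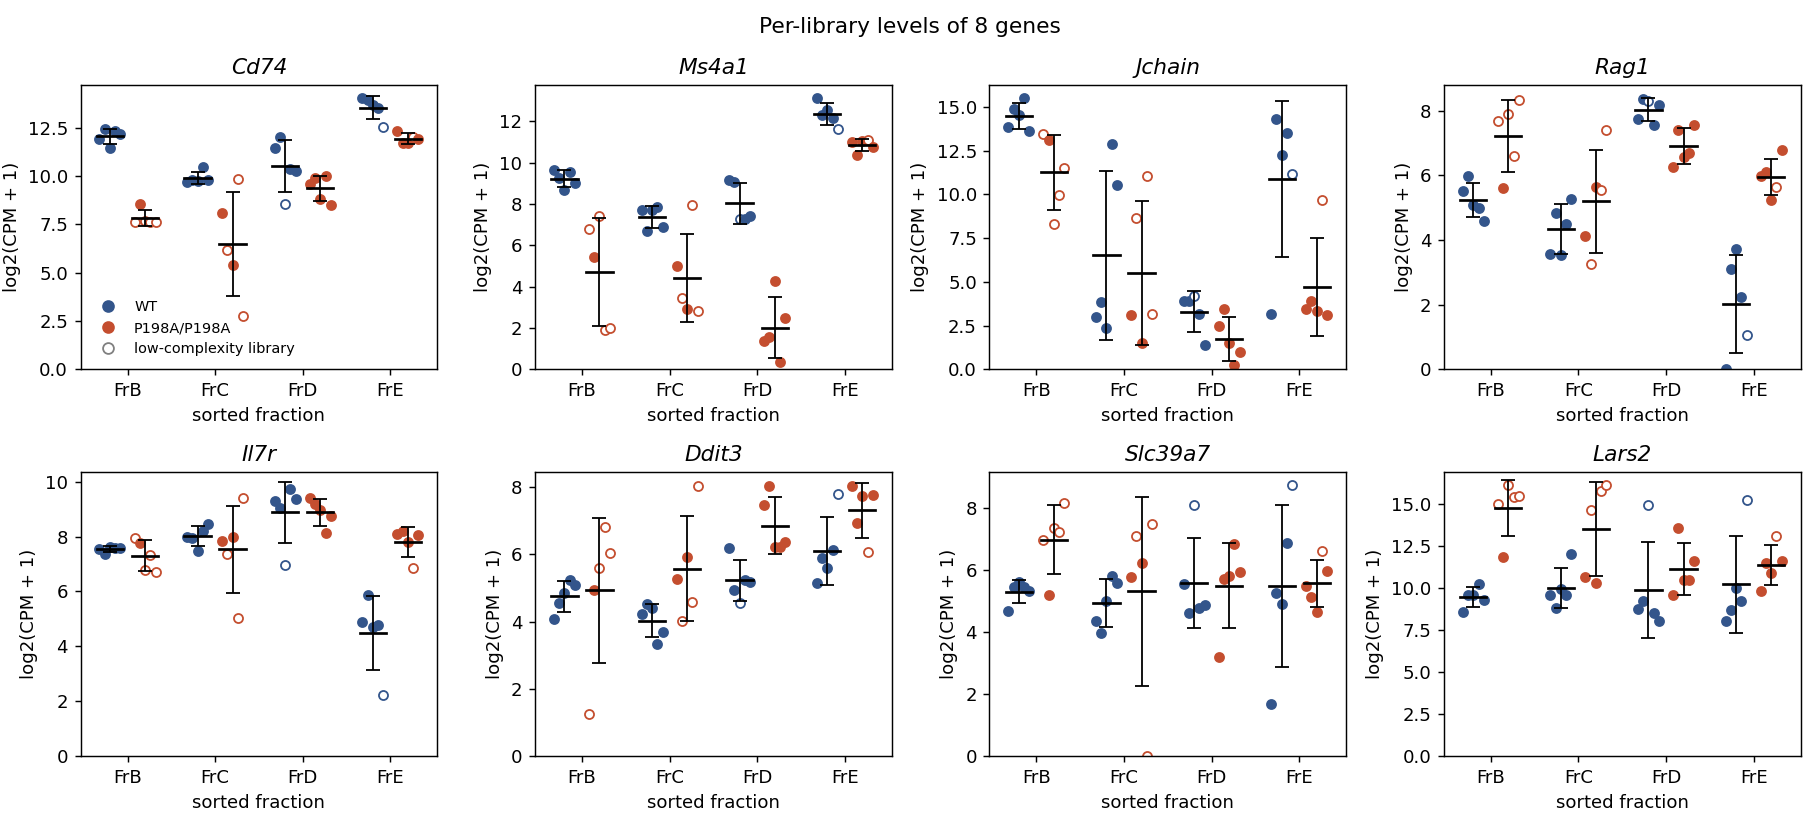
Level of 8 genes per library, as log2 of CPM plus 1 (y axis), in each sorted fraction (x axis), with WT and P198A/P198A libraries in separate colours, open points for low-complexity libraries and bars for the mean and SD of the plotted values (n = 5). Cd74 averages 4353.0 CPM in WT and 234.5 CPM in mutant FrB, and 12611.0 and 3955.0 CPM in FrE.

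In FrD, the late pre-B stage, Tnfrsf13c was the only gene called by edgeR of 10043 tested. The gene (ENSMUSG00000068105, chromosome 15, 82221743 to 82224369) encodes the receptor for the survival factor BAFF and fell from 290.3 ± 80.3 to 51.2 ± 13.1 CPM (SD, n = 5 each), a log2 fold change of -2.49 ± 0.32 (SE, adjusted p = 0.021). Immature and mature B genes were lower as a list, with 22 of 25 below 0, 1 called over all genes, 6 adjusted over the list alone and a median of -1.13 (camera adjusted p = 3.25e-10, and adjusted p = 0.196 with an estimated correlation). Ms4a1, the gene of CD20, was at 5.4 ± 7.4 CPM in mutants and 313.9 ± 212.8 in WT (SD, n = 5 each), with an adjusted p of 0.149. Blnk, an adaptor of pre-B cell receptor signalling, stood at -1.39 ± 0.25 (SE, adjusted p = 0.149).

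Stress response genes were higher in mutant FrD. All 18 tested members of the integrated stress response lay above 0, with a median of 1.41 and none called singly (camera adjusted p = 4.4e-07, and 0.0383 with an estimated correlation). Ddit3 (ENSMUSG00000025408, chromosome 10, 127290774 to 127296288) was at 132.0 ± 82.7 CPM in mutants and 39.2 ± 19.3 in WT (SD, n = 5 each, adjusted p = 0.518), and the serine metabolism gene Shmt2 stood at 2.1 (adjusted p = 0.825). Of 30 unfolded protein response genes 25 lay above 0, with a median of 0.53 and 1 called when adjusted over the list alone (camera adjusted p = 1.29e-06, and 0.0121 with an estimated correlation). The endoplasmic reticulum chaperone Hspa5 stood at 1.04 ± 0.26 (SE, adjusted p = 0.438). Markers of granulocytes and monocytes were also higher, 11 of 19 above 0 and 3 called when adjusted over the list alone, at a median of 0.61 (camera adjusted p = 1.53e-07, and adjusted p = 0.108 with an estimated correlation). Without the low-complexity library of WT mouse 3 their median was 5.97, with 19 of 19 above 0 (camera adjusted p = 1.18e-05, and adjusted p = 0.135 with an estimated correlation).

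Cell cycle and recombination lists moved less in mutant FrD. G2/M genes were lower at a median of -0.44, 30 of 35 below 0 (camera adjusted p = 1.37e-06, and adjusted p = 0.392 with an estimated correlation), although the median was 0.11 under ERCC scaling. G1/S genes were higher at a median of 0.08, which was -0.03 with size factors (camera adjusted p = 0.0414, and adjusted p = 0.561 with an estimated correlation). V(D)J recombination genes were lower at a median of -0.46, 2 called when adjusted over the list alone, and at 0.09 under ERCC scaling (camera adjusted p = 0.0207, and adjusted p = 0.349 with an estimated correlation). FOXO targets were lower at -0.35, and at 0.09 under ERCC scaling (camera adjusted p = 0.000563, and adjusted p = 0.152 with an estimated correlation). Glycolysis genes were higher at 0.36 (camera adjusted p = 0.0295, and adjusted p = 0.631 with an estimated correlation) and cholesterol synthesis genes at 0.38 (camera adjusted p = 0.0292, and adjusted p = 0.532 with an estimated correlation; 0.14 without low-complexity libraries). Erythroid genes ranked higher by the test while their median was -0.51 and their mean -0.60 (camera adjusted p = 0.000722, and adjusted p = 0.532 with an estimated correlation). Without low-complexity libraries the medians of G1/S, glycolysis, cholesterol synthesis and erythroid genes were 0.47, 0.79, 0.25 and 0.96. Tnfrsf13c kept its direction but had an adjusted p of 0.0531 to 0.172 without mouse 1, 2, 4, 5, 6, 8, 9 or 10 in turn, 0.681 under ERCC scaling, 0.0644 in the joint fit and 0.0556 with the second-index covariate. FrD calls numbered 0 without mouse 1, 2, 4, 5, 6, 9 or 10, 2 without mouse 7, 39 without WT mouse 3, 11 in the joint fit, 69 with DESeq2 and 149 with voom.

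In FrE, the immature B stage, edgeR called 0 genes of 9662, with 512 at an unadjusted p under 0.05. DESeq2 called 58 and voom 10. Immature and mature B genes were lower as a list, 24 of 26 below 0 and 14 called when adjusted over the list alone, at a median of -1.13 (camera adjusted p = 1.37e-24, and 0.0105 with an estimated correlation). Cd74 was at 3955.0 ± 769.8 CPM in mutants and 12611.0 ± 4311.0 in WT (SD, n = 5 each), a value of -1.65 ± 0.28 (SE, adjusted p = 0.127). H2-DMb2, which acts in MHC class II peptide loading, stood at -1.70 ± 0.30 and Ms4a1 at -1.54 ± 0.29 (SE, both adjusted p = 0.127). Pro-B and progenitor genes were higher as a list, 5 called higher and 1 lower when adjusted over the list alone, at a median of 0.74 (camera adjusted p = 0.000618, and 0.0495 with an estimated correlation). Il7r, the interleukin-7 receptor, was at 234.4 ± 72.7 CPM in mutants and 28.2 ± 19.2 in WT, and Rag2 at 110.1 ± 52.0 and 4.8 ± 3.7 CPM (SD, n = 5 each, both adjusted p = 0.127). Rag1 was at 64.8 ± 27.1 and 5.0 ± 5.0 CPM (SD, n = 5 each, adjusted p = 0.431), and Atp1b1 stood at 2.06 ± 0.35 (SE, adjusted p = 0.127). The plasma cell gene Jchain stood at 2303.6 to 20360.1 CPM in WT FrE of mice 2, 3, 6 and 7 and at 8.1 in mouse 1. In mutant FrE it stood at 7.5 to 14 CPM in mice 4, 5, 8 and 10 and at 816.1 in mouse 9. Cell mixture may thus differ between the genotypes in FrE, which was not tested.

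Other lists in FrE split in direction. G2/M genes were higher, 34 of 35 above 0, at a median of 0.76 (camera adjusted p = 1.08e-08, and adjusted p = 0.465 with an estimated correlation). Mki67, a proliferation marker, was at 272.9 ± 125.5 CPM in mutants and 111.3 ± 56.0 in WT (SD, n = 5 each, adjusted p = 0.851). G1/S genes were lower, 32 of 34 below 0, at a median of -0.77 (camera adjusted p = 1.43e-06, and adjusted p = 0.399 with an estimated correlation). The integrated stress response was higher at a median of 0.76 (camera adjusted p = 2.77e-05, and adjusted p = 0.211 with an estimated correlation), with Atf4 at 1.01 ± 0.32 (SE, adjusted p = 0.674). FOXO targets were higher at 0.18, and at -0.09 under ERCC scaling (camera adjusted p = 0.0275, and adjusted p = 0.399 with an estimated correlation). Interferon response genes were lower at -0.39 (camera adjusted p = 0.00222, and adjusted p = 0.362 with an estimated correlation), and heat shock and handling genes at -0.53 (camera adjusted p = 0.0275, and adjusted p = 0.211 with an estimated correlation; 0.062 without low-complexity libraries). Granulocyte and monocyte genes stood at a median of 3.07, 11 of 12 above 0, while the test pointed lower (camera adjusted p = 0.627). Against WT, mutant mice 5 and 9 stood at 6.90 and 5.92 for them and mice 4, 8 and 10 at -0.80, -2.63 and -2.25. Without low-complexity libraries their median was 1.69, that of pro-B genes 0.42 and that of FOXO targets 0.34. Calls in FrE numbered 21 without WT mouse 7, which has a low-complexity library, and 28 without both libraries of that kind, among them Cd74, Ms4a1, Tnfrsf13c, Rag2 and Il7r.

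**Figure D3:**
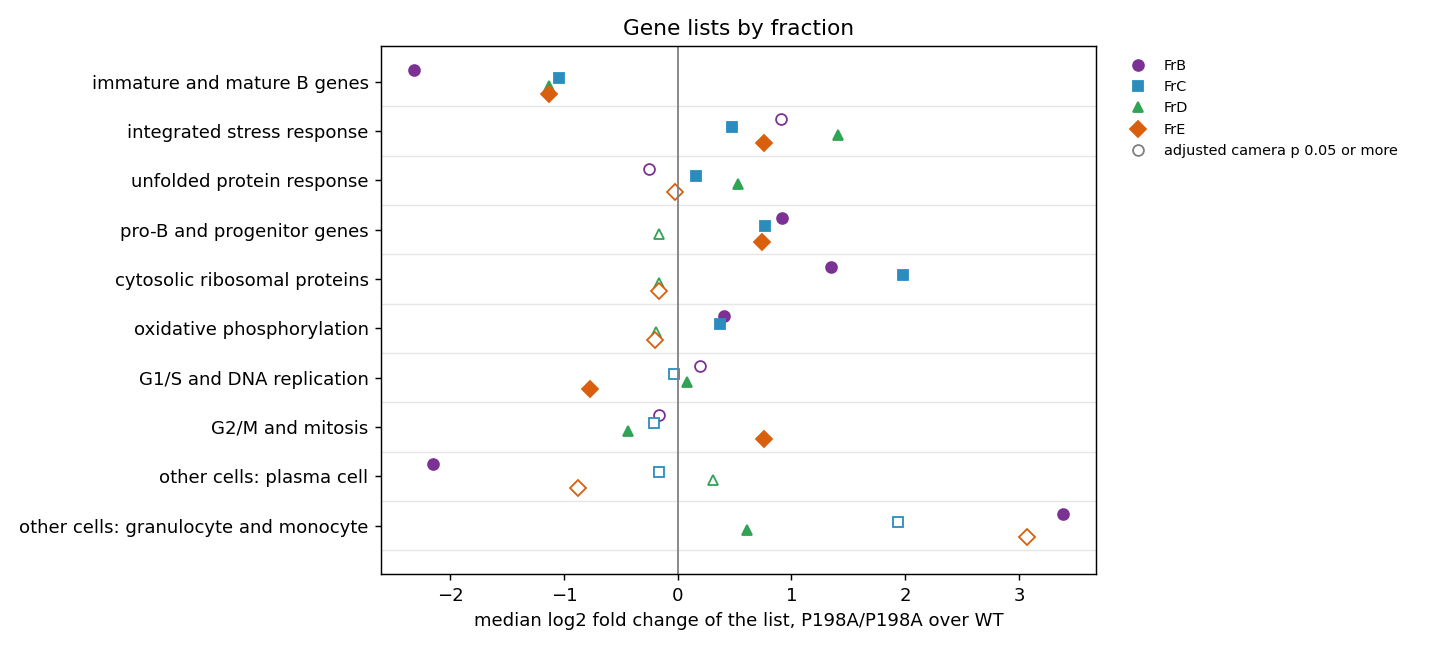
Median log2 fold change of mutant over WT (x axis) for 10 gene lists (y axis) in each fraction, with open points where the adjusted camera p was 0.05 or more. Immature and mature B genes lie below 0 in all 4 fractions, at -2.32, -1.04, -1.13 and -1.13, and keep that sign under size factors and ERCC scaling.

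Summed over the fractions of each mouse, 35 genes were higher and 41 lower in mutants of 12036 tested. The sums weight each fraction by its depth, which differs between mice and genotypes (for mutant mouse 9, 43372070 counts in FrD and 42111 in FrE), so genes that differ between stages can differ in the sums through these shares alone. With equal weight to the 4 fractions and the mouse as a random effect, 20 of the 23 named calls held, Ddit3 at 1.28, Atf4 at 0.83 and Cd74 at -2.79, while Cox6a2 (adjusted p = 0.0509), Clec4a2 (0.223) and Cacna1s (0.061) did not. Ddit3 rose by 1.65 ± 0.19 (SE, adjusted p = 0.000856) and Atf4 (ENSMUSG00000042406, chromosome 15, 80255184 to 80257541) by 0.78 ± 0.12 (SE, adjusted p = 0.00754). With Mthfd2, a mitochondrial folate enzyme (0.81 ± 0.16, SE, adjusted p = 0.0347), 3 of 20 integrated stress response genes rose, and 10 rose and 1 fell when adjusted over the list alone (median 0.79, camera adjusted p = 8.66e-06, and adjusted p = 0.0801 with an estimated correlation). Cox6a2, a cytochrome oxidase subunit, rose by 1.68 ± 0.20 (SE, adjusted p = 0.000938), the transcription factor gene Bach2 by 1.11 and the isoleucyl-tRNA synthetase gene Iars by 1.22. Clec4a2 (2.90), Slc7a1 (1.5), Lgr5 (1.07), Ano6 (1.0) and Elk4 (0.95) were also among those of lowest p.

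Lower over all fractions were 6 of 26 immature and mature B genes, and 19 when adjusted over the list alone (median -1.26, camera adjusted p = 7.07e-19, and adjusted p = 0.0801 with an estimated correlation). They included the MHC class II genes H2-Eb1 (-1.79 ± 0.22, SE, adjusted p = 0.00101), Cd74 (-1.98 ± 0.26, SE, adjusted p = 0.00236) and H2-Ab1 (-1.29) and the B cell adaptor Bank1 (-1.54). Fah (ENSMUSG00000030630, chromosome 7, 84585159 to 84606722) had a value of -9.28 ± 0.88 (SE, adjusted p = 0.000144), with WT levels of 29.0 ± 11.4, 1.6 ± 1.1, 6.3 ± 6.3 and 26.3 ± 32.8 CPM in FrB, FrC, FrD and FrE (SD, n = 5 each) and at most 0.1 CPM in any mutant library. Txndc5, a protein disulfide isomerase of the endoplasmic reticulum, fell by 1.62 ± 0.18 (SE, adjusted p = 0.00067) and the lymphocyte GTPase gene Gimap4 by 2.31 ± 0.28 (SE, adjusted p = 0.00101). Cacna1s (-6.54), Pon3 (-2.42), H2-Oa (-1.81) and Cyb561a3 (-1.48) were among the others of lowest p. Ribosomal protein genes were higher at a median of 0.37 (0.16 without low-complexity libraries), 2 of 86 called and 33 adjusted over the list alone (camera adjusted p = 2.58e-17, and adjusted p = 0.784 with an estimated correlation). Granulocyte and monocyte genes were higher at 2.25, 0 of 21 called by edgeR and 2 adjusted over the list alone (camera adjusted p = 8.35e-10, and adjusted p = 0.536 with an estimated correlation). Lower were G2/M genes at -0.18 (camera adjusted p = 0.0282, and adjusted p = 0.845 with an estimated correlation) and plasma cell genes at -0.83 (camera adjusted p = 0.0282, and adjusted p = 0.784 with an estimated correlation). Total calls were 30, 26, 27 and 34 without mouse 1, 2, 6 or 10 and 39 without low-complexity libraries, 122 without a filter, 533 with DESeq2 and 433 with the mouse as a random effect. Of the genes named, Mthfd2 (adjusted p = 0.114), Bank1 (0.129), Slc7a1 (0.145), Elk4 (0.155) and Iars (0.0545) were not called without low-complexity libraries.

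**Figure D4:**
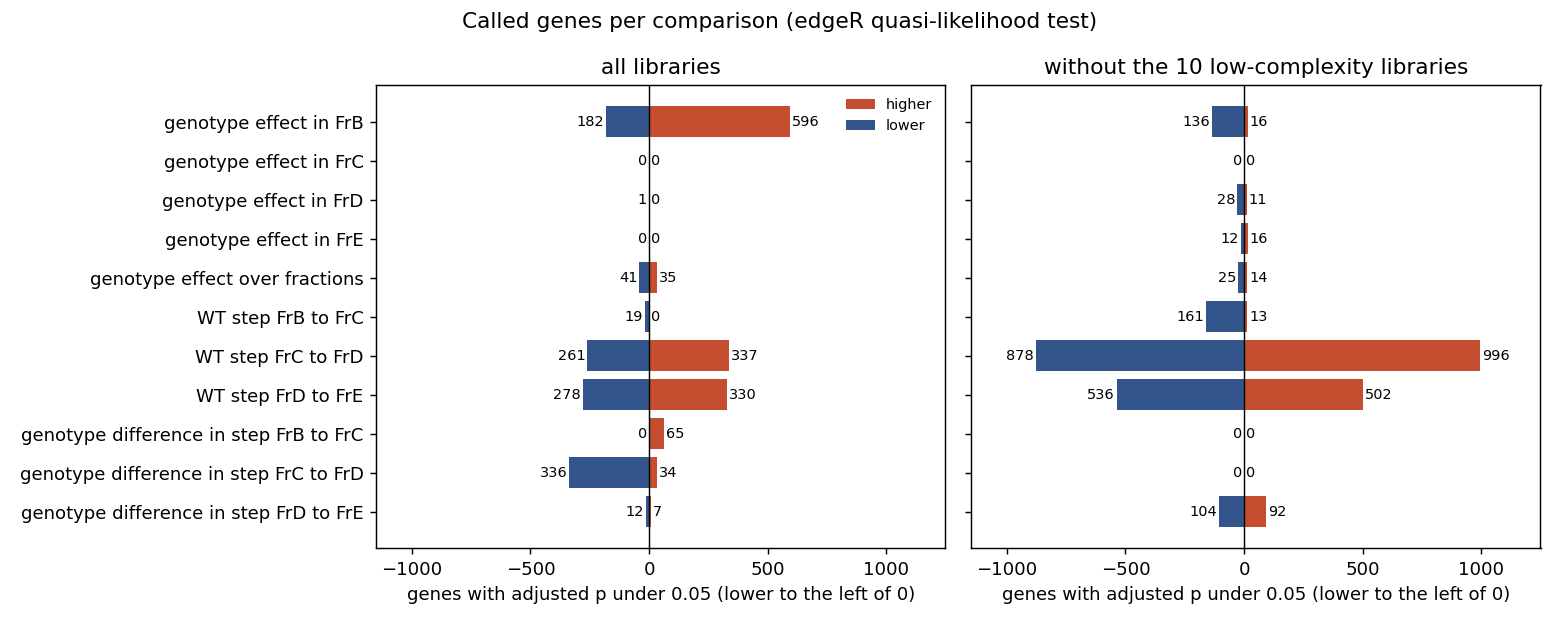
Number of genes with an adjusted p under 0.05 per comparison (x axis, higher to the right of 0 and lower to the left) by the edgeR test, with all libraries and without the low-complexity ones. In FrB the numbers are 596 higher and 182 lower with all libraries and 16 and 136 without.

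The WT steps compare sorted fractions of the chimeras, which can differ in cell mixture as well as in stage. Jchain, a plasma cell gene, stood at 12666.1 to 46176.7 CPM in WT FrB and at 4.2 to 7598.5 CPM in WT FrC. From FrB to FrC 0 genes rose and 19 fell of 11439 tested with edgeR, with 576 at an unadjusted p under 0.05, and DESeq2 called 148 and voom 1079. Fcmr fell by 2.85 ± 0.36 and Bhlhe41, a repressor of the circadian clock, by 3.72 ± 0.48 (SE, both adjusted p = 0.000492). Cd83 (-3.35), Rnase6 (-2.52), Shisa5 (-2.48), Ltb (-2.12), Lsp1 (-1.61), Ly6d (-1.61) and Cyba (-1.29) fell as well. Of 26 immature and mature B genes 4 fell, Cd74 by 2.16, and 17 fell and 2 rose when adjusted over the list alone (median -1.70, camera adjusted p = 9.06e-17, and 0.0337 with an estimated correlation). Of 30 unfolded protein response genes 3 fell, Xbp1 by 2.57 ± 0.44 (SE, adjusted p = 0.00786), Creld2 and Edem1, and 13 when adjusted over the list alone (median -0.92, camera adjusted p = 1.76e-21, and 0.0116 with an estimated correlation). G1/S genes were higher at 0.46 (camera adjusted p = 2.14e-07, and adjusted p = 0.143 with an estimated correlation), and G2/M genes at 0.33 (camera adjusted p = 2.82e-06, and adjusted p = 0.314 with an estimated correlation). Interferon response genes were lower at -1.52 (camera adjusted p = 2.71e-09, and 0.0343 with an estimated correlation) and FOXO targets at -0.59 (camera adjusted p = 0.00116, and 0.0433 with an estimated correlation), the latter at 0.08 under ERCC scaling.

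Markers of other cells were lower in WT FrC than in WT FrB. Plasmacytoid dendritic cell genes stood at a median of -3.29, with 2 of 11 called, Rnase6 and Ly6d, which B-lineage cells also express, and 8 adjusted over the list alone (camera adjusted p = 5.44e-16, and 0.0109 with an estimated correlation). Plasma cell genes stood at -2.89, with 2 of 8 called, Xbp1 and Mzb1 (camera adjusted p = 7.53e-09, and 0.0433 with an estimated correlation). Those of granulocytes and monocytes stood at -3.33, with 1 of 18 called, Ly6c2 (camera adjusted p = 2.39e-08, and adjusted p = 0.152 with an estimated correlation). Erythroid genes stood at -2.35 (camera adjusted p = 6.98e-08, and adjusted p = 0.171 with an estimated correlation). T cell genes were lower at -1.37, though at 0.45 under ERCC scaling (camera adjusted p = 0.0254, and adjusted p = 0.262 with an estimated correlation), and so were NK cell genes (camera adjusted p = 0.0452, and adjusted p = 0.318 with an estimated correlation). Oxidative phosphorylation genes were higher (camera adjusted p = 0.0186, and adjusted p = 0.494 with an estimated correlation), as were glycolysis genes (camera adjusted p = 0.0252, and adjusted p = 0.269 with an estimated correlation). Calls from FrB to FrC numbered 3, 4 and 10 without mouse 1, 2 or 6, 0 under ERCC scaling and 1 in the joint fit, and 174 without low-complexity libraries.

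From FrC to FrD 337 genes rose and 261 fell of 11439 tested. Btg1, which restrains proliferation, rose by 2.91 ± 0.22 (SE, adjusted p = 6.7e-08), and its relative Btg2 by 2.54. Dnajc7 (3.56), Slfn2 (4.25), Rnase6 (3.41), Ly6d (3.06), Cd38 (2.99), Sema4b (2.78), Rgs2 (2.73) and Cd79b (2.01) had the next lowest p. Of 19 FOXO targets 8 rose, and 13 when adjusted over the list alone, at a median of 1.46 (camera adjusted p = 5.37e-14, and 0.000137 with an estimated correlation), which was -0.99 under ERCC scaling. They included Rag1 (3.60 ± 0.75, SE, adjusted p = 0.00554), Klf2 (3.26), S1pr1 (2.62) and Foxo1 (1.88). Under ERCC scaling Foxo1 stood at -0.20 and Cd79b at -0.54. Among the genes that fell were Cdk6, a G1 kinase (-2.96 ± 0.38, SE, adjusted p = 5.83e-05), Myc (-6.02 ± 0.98, SE, adjusted p = 0.000763), the D cyclins Ccnd2 (-3.73) and Ccnd3 (-1.78), Phgdh (-3.10), Pa2g4 (-2.26) and Vpreb1 (-3.66). Of 20 glycolysis genes 6 fell, Pkm by 2.21 ± 0.37 (SE, adjusted p = 0.000907), and 8 when adjusted over the list alone, at a median of -1.35 (camera adjusted p = 2.6e-06, and adjusted p = 0.0878 with an estimated correlation).

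Further lists rose from WT FrC to FrD relative to all genes, though each of the next 6 had a median below 0 under ERCC scaling. Immature and mature B genes stood at 1.05 with 7 of 26 called (camera adjusted p = 7.64e-07, and adjusted p = 0.258 with an estimated correlation). BCR signalling stood at 0.56 with 6 of 36 called (camera adjusted p = 0.0177, and adjusted p = 0.495 with an estimated correlation), and V(D)J recombination at 0.40 with 2 of 13 called (camera adjusted p = 0.03, and adjusted p = 0.258 with an estimated correlation). Immediate early genes stood at 1.39 with 4 called higher and 1 lower of 19 (camera adjusted p = 0.00447, and adjusted p = 0.258 with an estimated correlation). Pre-B transcription factors stood at 0.54 with 4 called higher and 1 lower of 21 (camera adjusted p = 0.00133, and adjusted p = 0.146 with an estimated correlation). Interferon response genes stood at 1.16 with 3 of 30 called (camera adjusted p = 0.00702, and adjusted p = 0.402 with an estimated correlation). Granulocyte and monocyte genes stood at 3.49 with 3 of 18 called (camera adjusted p = 0.00533, and adjusted p = 0.495 with an estimated correlation), and plasmacytoid dendritic cell genes had 4 of 11 called higher (camera adjusted p = 0.000125, and adjusted p = 0.258 with an estimated correlation). G1/S genes were lower at -0.59 with 0 of 34 called by edgeR (camera adjusted p = 6.73e-05, and adjusted p = 0.258 with an estimated correlation). G2/M genes were lower with 1 of 35 called, Cdc20 (camera adjusted p = 0.0232, and adjusted p = 0.733 with an estimated correlation), and so were heat shock genes (camera adjusted p = 0.0177, and adjusted p = 0.258 with an estimated correlation). ERCC scaling, under which the median of all genes moved from 0.09 to -2.39, gave 40 genes higher and 6596 lower. Calls numbered 188, 237 and 324 without mouse 1, 2 or 6, 175 in the joint fit and 1874 without low-complexity libraries, where the medians of BCR signalling, granulocyte and G1/S genes were 0.30, 0.76 and -1.09.

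From FrD to FrE 330 genes rose and 278 fell of 11439 tested, and with the mouse as a block 176 rose and 183 fell. Immature and mature B genes rose, 11 of 26 over all genes, with 16 up and 1 down when adjusted over the list alone and a median of 1.74 (camera adjusted p = 1.91e-23, and 0.0252 with an estimated correlation). Ms4a1 rose by 4.13 ± 0.43 (SE, adjusted p = 8.8e-06), Fcmr by 2.89 and Tnfrsf13c by 2.09 ± 0.29 (SE, adjusted p = 0.000123). Scd1, a fatty acid desaturase gene, had the lowest p (3.59 ± 0.30, SE, adjusted p = 4.32e-07), and Cfp (5.94), Plek (3.19), Ltb (2.81) and Mef2c (2.44) also rose. The recombinase genes Rag1 (-5.71 ± 0.82, SE, adjusted p = 0.000195) and Rag2 (-5.68 ± 0.80, SE, adjusted p = 0.000151) fell, with Il7r (-4.29 ± 0.53, SE, adjusted p = 5.11e-05) and Myb (-2.19). Slc12a3 (-3.53), Tifa (-3.17), Uchl1 (-3.02), Thbd (-2.80), Xrcc6 (-2.43), Cd93 (-2.09) and Elof1 (-1.95) were among the others. Of 35 G2/M genes 16 fell, Mki67 by 2.94, and 31 when adjusted over the list alone, with all 35 below 0 and a median of -1.89 (camera adjusted p = 6.49e-27, and 0.0435 with an estimated correlation).

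G1/S genes fell from WT FrD to FrE as well, 3 of 34 and 11 when adjusted over the list alone, at a median of -1.27 (camera adjusted p = 3.54e-10, and adjusted p = 0.0554 with an estimated correlation). Of 18 pro-B and progenitor genes 6 fell, at a median of -0.81, or -0.67 with the member without counts at its bound (camera adjusted p = 0.000201, and 0.0435 with an estimated correlation). V(D)J recombination genes fell in 4 of 13 cases, at -0.56 (camera adjusted p = 0.000753, and adjusted p = 0.0554 with an estimated correlation), and FOXO targets in 4 of 19, at -0.73 (camera adjusted p = 0.000753, and 0.0435 with an estimated correlation). Of 30 unfolded protein response genes 7 rose, among them Calr (1.31) and Hspa5 (1.21), and 12 rose and 1 fell when adjusted over the list alone, at a median of 0.94 (camera adjusted p = 8.9e-06, and adjusted p = 0.272 with an estimated correlation). BCR signalling had 4 genes higher and 1 lower of 36 (camera adjusted p = 0.00112, and adjusted p = 0.363 with an estimated correlation). Cholesterol synthesis genes were higher at 0.71 (camera adjusted p = 0.0429, and adjusted p = 0.482 with an estimated correlation) and interferon response genes at 0.86 (camera adjusted p = 0.00429, and adjusted p = 0.363 with an estimated correlation). Oxidative phosphorylation genes were lower at -0.27, or 0.03 under ERCC scaling (camera adjusted p = 0.00259, and adjusted p = 0.482 with an estimated correlation). ERCC scaling gave 177 genes higher and 62 lower. Calls numbered 272 and 252 without mouse 1 or 6, 254 in the joint fit, 1472 with DESeq2 and 1038 without low-complexity libraries, where pro-B and V(D)J recombination genes both had a median of -1.30.

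Whether the mutation changed these steps was tested as a difference of differences over 12397 genes. From FrD to FrE 7 genes had a higher and 12 a lower step in mutants. Rag1 had a difference of 4.79 ± 1.0 (SE, adjusted p = 0.0353). It went from 266.1 ± 60.8 to 5.0 ± 5.0 CPM in WT and from 126.2 ± 49.8 to 64.8 ± 27.1 in mutants (SD, n = 5 each). Dnajc7 (2.55) and Psme4 (2.62) went down in WT, from 2031.2 to 479.1 and from 316.7 to 60.2 CPM, while mutant means were 630.7 and 871.0 for the former and 127.5 and 147.2 for the latter. Cfp, properdin of the complement system, had a difference of -6.56, from 6.3 to 394.6 CPM in WT and from 67.4 to 53 in mutants. From FrB to FrC 65 genes had a higher step in mutants and from FrC to FrD 34 a higher and 336 a lower one. Several of these rested on FrC means with an SD above the mean, such as Thoc6 at 8150.5 ± 17919.9, Mdh1 at 8427.6 ± 17331.2 and Blnk at 5173.7 ± 10444.9 CPM in mutant FrC (SD, n = 5). With the mouse as a block the calls for the steps in order were 0, 1 and 0, and without low-complexity libraries 0, 0 and 196, and with size factors the last step had 6 higher and 17 lower. Calls in the first step numbered 0 without mouse 1, 2, 3, 6, 7 or 9, 381 without mouse 5 and 133 without mouse 10. In the second they were 0 without mouse 1, 2, 3, 6 or 9 and 144 without mouse 7, and in the last 5, 0, 1, 9, 2, 3, 39 and 1 without mouse 1, 2, 4, 6, 7, 8, 9 or 10.

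Several lists did not pass in any genotype effect or WT step. The lowest camera adjusted p over these comparisons was 0.0685 for oxidative stress, 0.0738 for the pre-BCR and BCR complex, 0.0801 for megakaryocytes, 0.0866 for apoptosis regulators and 0.0929 for IL-7 and STAT5 targets. It was 0.107 for p53 targets, 0.109 for basophils, mast cells and eosinophils, 0.135 for metallothioneins and MTF1 targets, 0.149 for tyrosine phosphatases, 0.217 for zinc transporters and 0.302 for stroma. The pre-BCR and BCR complex list had 6 of its 12 given members in the counts and lacked the immunoglobulin chain genes. Of 81 list calls in all comparisons 16 held with an estimated correlation. Fold changes are relative to TMM scaling. Under ERCC scaling the median of all genes moved from 0.11 to 0.59 for the genotype effect in FrB, from 0.09 to 0.26 in FrC, from -0.07 to 0.39 in FrD and from -0.10 to -0.24 in FrE. With size factors it was 0.25 in FrC. For the WT steps from FrB to FrC and from FrD to FrE the medians moved from 0.01 to 0.74 and from 0.01 to 0.29 under ERCC scaling.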

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

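The tests on low-complexity libraries, mature B cells, granulocytes and handling in this part were chosen only after the results were seen, while the tests on GC content and transcript length and on other splits of the samples were planned.

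The 596 genes higher in mutant FrB are the first pattern. A trend with GC content or transcript length as the whole cause is argued against: of 479 of these genes that limma called, 275 (57.4%) stayed called after the trend was removed from each library, with medians of 2.07 and 2.09. Chance is also argued against, since 1 of 100 splits of the samples, the real one, gave as many as 778 calls and the highest other gave 80. Low library complexity is a candidate explanation: in the WT libraries of low complexity the same genes stood at 1.95 above the rest of their groups on average (2.13 in FrD of mouse 3, 1.77 in FrE of mouse 7), and without such libraries their median was 0.78 against 2.37 with them, and 14 stayed called. An effect of the mutation stays open and untested apart from it, as 4 of 5 mutant FrB libraries have low complexity and the genes were chosen partly on the remaining one, that of mouse 5.

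The 182 genes lower in mutant FrB are the second pattern, which includes Cd74, Fcmr and Tnfrsf13c. Low complexity may account for part of it, since the same genes stood at -1.75 on average in the WT libraries of low complexity (-1.89 and -1.60, against -3.09 for the called genes in FrB). Without low-complexity libraries their median was -2.64 and 63 stayed called, so the lost calls go with fewer libraries more than with a smaller fold, but the 1 mutant library left is one on which the genes were chosen and does not separate the sources. A smaller share of mature B cells inside the mutant gate is another candidate explanation, although the sort for B220, CD43 and CD24 without BP-1 is meant to leave such cells out of FrB and the labels give no IgM or IgD gate for it, as these genes stood at a median of 0.49 in the step from WT FrD to FrE while matched random sets had a median of -0.12 and a 95th percentile of -0.01. Of the 182 genes, 24 were called higher and 3 lower in WT FrE than in WT FrD, and their median from WT FrB to FrC was -1.16. Lower expression per cell in mutants stays open as well and was not tested. The WT step cannot separate it from a smaller share of mature B cells, since either could lower genes that rise toward FrE. WT FrE also held plasma cell RNA, with Jchain at 2303.6 to 20360.1 CPM in mice 2, 3, 6 and 7. In FrB Jchain stood at 12666.1 to 46176.7 CPM in WT and at 322 to 11258.6 in mutants. A difference in plasma cells inside the gate is therefore open too and was not tested.

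Higher integrated stress response genes in mutants, with Ddit3 and Atf4 called over all fractions, are the third pattern. Against low complexity in FrD, the median was 1.61 without such libraries, with 19 of 19 genes above 0, and against cell handling stress, the medians of the heat shock and handling list and of immediate early genes averaged -0.32 over FrD and FrE. In FrE the tables argue against it as well: without those libraries the median was 0.79 against 0.76 with them, and the members changed by a median of -0.11 (quartiles -0.18 and 0.12), by a rule set after an earlier one on the share of genes above 0 (12 of 16) had left it undecided. Granulocyte and monocyte RNA as the whole cause is argued against in FrE, where the fit put those markers at 3.07 but the median over mutant libraries was -0.80: mice 4, 8 and 10 stood at -0.80, -2.63 and -2.25 for them and at 1.41, 1.38 and 1.33 for the stress genes, against 6.90 and 0.88 in mouse 5 and 5.92 and 0.06 in mouse 9 (a rule per library, set after these values were seen and an earlier rule on the fit had left it undecided). FrE of WT mouse 6 also stood at 1.58 for the stress genes (quartiles 0.20 and 2.85) and at -2.06 for the markers. Such a profile is therefore not particular to mutants, although the other WT FrE libraries stood at -1.06 to 0.39 for the stress genes. Mutant mice 4, 8 and 10 also share their set of second indices with WT mice 2 and 6. WT mouse 2 stood at -2.47 for the markers and at 0.16 for the stress genes. In the other set, that of mutant mice 5 and 9, WT mice 1, 3 and 7 stood at 0.06, 3.06 and 1.05 for the markers. Marker levels thus went with the index set, of which the rule took no account. In FrD granulocyte and monocyte RNA cannot be told apart from the mutation, which the design names and which stays open in both: the markers had a median of 2.91 over mutant libraries and of 0.61 in the fit (quartiles -1.19 and 2.03), and of 5.97 with 19 of 19 above 0 without the library of WT mouse 3, which had the markers (3.04) with stress genes at 0.29.

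The other splits of the samples were counted for each further comparison, with the real split included. For the genotype effects in FrC and FrE the real count of 0 is reached by all 100 splits by construction (highest others 5 and 3), so the splits say nothing about chance there. For FrD 3 of 100 splits gave at least the real 1 call (highest other 2), and over fractions 1 of 100 gave the real 76 (highest other 1). For the WT steps, 1 of 100 gave the real 19 from FrB to FrC (highest other 0), 1 the real 598 from FrC to FrD (highest other 93) and 2 the real 608 from FrD to FrE (highest other 799). That other split exchanged FrD of mouse 3 with FrE of mouse 2. Of the 11 drawn splits that part all 5 pairs of a mouse, the real one alone was as large in each step, the highest others being 0, 0 and 63. For the differences of steps, 22 of 100 splits gave the real 65 from FrB to FrC (highest other 255), so chance is not excluded there and the splits point to a structure of the samples. For the later steps 3 of 100 gave the real 370 (highest other 404) and 2 the real 19 (highest other 42). These splits leave out the mouse, and with the mouse as a block the calls fell to 1 and 0, so chance is not taken as excluded for either.

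A single library lay far from the rest of its group in 37 of 152 groups tested. The rule used cut-offs made for normal values, where chance gives about 1 in 20 groups. CPM values are skewed and the groups share the same 40 libraries, so no excess over chance is claimed. Total counts were 6372181 in FrD of WT mouse 3 and 42111 in FrE of mutant mouse 9, which also had 7365 genes detected. The 50 highest genes held 21.3% of counts in FrB of WT mouse 6 and 25.3% in FrD of WT mouse 3. That WT FrD library also stood apart for Slc39a7 (277.3 CPM), Rag2 (13.9), S100a8 (44244.7), Lars2 (30607.3) and Mki67 (2780.8). FrE of WT mouse 7 stood apart for Slc39a7 (428.4 CPM), Lars2 (37178.7) and Ddit3 (220.1). In other WT libraries the far values in CPM were Cd74 1407.4 and Jchain 7598.5 in FrC of mouse 6, S100a8 109.4 in FrC of mouse 1 and 558.4 in FrE of mouse 3, Lars2 4068.3 in FrC of mouse 7, Igll1 803.2 in FrE of mouse 2 and Ddit3 72.3 in FrD of mouse 1.

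In mutant FrC the library of mouse 9 stood apart for Cd74 (920.8 CPM), Ms4a1 (242.8), Igll1 (27847.1) and Jchain (2166.8), that of mouse 10 for Rag1 (169.5) and Ddit3 (261.6), and that of mouse 5 for S100a8 (11992.8). In mutant FrB mouse 5 stood apart for Cd74 (376.2 CPM). In mutant FrD the far values in CPM were Ms4a1 18.3 in mouse 8, Fah 0.1 in mouse 4, and Lars2 11890.3, Mki67 866.6 and Atf4 639.8 in mouse 5. In mutant FrE they were S100a8 16541.6 in mouse 5, Fah 0.1 in mouse 8, and Lars2 8454.9 and Jchain 816.1 in mouse 9.

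Named genes whose steps differed between genotypes were, from FrB to FrC, Mfsd14b (6.26), Mrps26 (5.26), Mdh1 (4.78), Thoc6 (7.31), Sar1a (4.95), Klhl14 (6.4), Cd2 (3.74), Wdr1 (4.93), Rrm2b (4.59) and Timd2 (18.59), all with an adjusted edgeR p of 0.0395. From FrC to FrD they were Pycr1 (10.12), Ppih (-5.86), Blnk (-4.50), Rabep1 (-7.57), Bcl2l1 (-5.96), Scaf11 (-4.90), Cdc34 (-6.45), Ndufc1 (-4.14), Csnk1a1 (-4.40) and Cmip (-5.62), all at 0.0232. From FrD to FrE they were Ttll11 (-14.54), Dctd (-16.19), Neurl1b (8.88), Zfp523 (-15.75), Gcsam (-15.75), Rag1 (4.79), Chst1 (-15.23), Dnajc7 (2.55), Cfp (-6.56) and Psme4 (2.62), at 0.0177 to 0.0375. Fitted values of Timd2, Pycr1, Ttll11, Dctd, Zfp523, Gcsam and Chst1 involve groups at or near 0 counts and are no bounds. With the mouse as a block these steps had 0, 1 and 0 calls. Without low-complexity libraries none of the first 20 was called: Mfsd14b stood at 1.26, Mrps26 and Mdh1 at 0.12, Thoc6 at 0.65, Sar1a at 0.53, Klhl14 at 8.55, Cd2 at 2.70, Wdr1 at 0.22, Rrm2b at 0.54 and Timd2 at 20.42, and Pycr1 at 9.31, Ppih at -0.79, Blnk at -1.34, Rabep1 at -0.84, Bcl2l1 at -0.05, Scaf11 and Cdc34 at -0.13, Ndufc1 at -0.08, Csnk1a1 at -0.33 and Cmip at 0.50. All 10 of the last step stayed called, Rag1 at 4.54 and Dnajc7 at 2.61.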

How the results depend on the processing

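Fits without the low-complexity libraries were chosen after seeing the data, and the others were planned. Of the 190 calls of single named genes, 187 kept direction and significance with size factors, 168 without a filter, 147 with voom and 136 without low-complexity libraries. The same held for 172 of 172 that DESeq2 gave a p, 67 of 137 under ERCC scaling, 90 of 137 in the joint fit, 59 of 68 with the second-index covariate, 82 of 122 with the mouse as a block and 20 of 23 with the mouse as a random effect. Of 1440 such results with a mouse left out 1052 kept theirs, and the other 388 lost only significance. Counted per call, 104 of the 190 held with each mouse left out in turn, and 86 lost significance without at least 1 mouse. Of 81 list calls 16 held with an estimated correlation, 35 with fry and 69 without low-complexity libraries. In simulation the depth and spread let edgeR recover only 3.1% to 20.8% of genes changed 4-fold for the genotype effects within a fraction, so that a missing call sets no limit on smaller changes. The alternatives without immunoglobulin segments and without mitochondrial genes were not run, as the table holds 0 of either. For each result given in this part the cause was not tested, unless stated.

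For the genotype effects in FrB, FrC, FrD and FrE, total calls were 778, 0, 1 and 0. DESeq2 gave 1749, 174, 69 and 58, and without low-complexity libraries there were 152, 0, 39 and 28, where 1 mutant FrB library is assumed to vary like the others. Voom gave 3 in FrC, 149 in FrD and 10 in FrE, and the joint fit 627, 11 and 5. ERCC scaling gave 148 in FrB, 225 in FrC and 0 in FrD, and the second-index covariate 398 in FrB and 0 in FrD. Without a filter FrE had 5. The effect over fractions had 76 calls, 122 without a filter, 533 with DESeq2, 433 with the mouse as a random effect and 39 without low-complexity libraries.

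For the WT steps in order, calls were 19, 598 and 608. DESeq2 gave 148, 1294 and 1472, ERCC scaling 0, 6636 and 239, the joint fit 1, 175 and 254, and the fit without low-complexity libraries 174, 1874 and 1038. Voom gave 1079 from FrB to FrC and 2309 from FrC to FrD, and the mouse as a block gave 359 from FrD to FrE. For the differences of steps between genotypes, calls were 65, 370 and 19. DESeq2 gave 299, 611 and 473, voom 20, 4 and 91, no filter 0, 219 and 12, the mouse as a block 0, 1 and 0, and the fit without low-complexity libraries 0, 0 and 196. Size factors gave 187 in the first of these.

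Leaving out each mouse in turn gave 264 (without WT mouse 1) to 1937 (without mutant mouse 5) calls in FrB, 0 to 0 in FrC, 0 to 39 (without WT mouse 3) in FrD, 0 to 21 (without WT mouse 7) in FrE and 26 (without WT mouse 2) to 105 over fractions. It gave 3 (without mouse 1) to 22 from FrB to FrC, 188 (without mouse 1) to 669 from FrC to FrD and 252 (without mouse 6) to 498 from FrD to FrE. Differences of steps ranged from 0 to 381 (without mouse 5), from 0 to 431 and from 0 to 39 (without mouse 9). The genotype difference in log2 RNA per spike-in ranged from 0.43 to 1.05 in FrB, from -0.12 (without mouse 9) to 1.16 in FrC, from 0.04 to 0.68 in FrD and from -0.61 to -0.18 in FrE. In the WT steps it ranged from 0.54 to 0.71, from -2.32 to -2.11 and from -0.02 (without mouse 7) to 0.67. The fall from FrC to FrD passed in 0 of these 5, each with 4 libraries a group, for which the smallest exact permutation p is too high after adjustment. Without the 3 most abundant spike-ins that fall was -1.82 and did not pass, and the FrD difference was -0.02, while the FrC difference was -0.63 without low-complexity libraries.

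Signs turned for these named genes. Mpo had a log2 value of -1.97 in FrB without low-complexity libraries. Slc39a7 had a log2 value of -0.15 in FrB and 0.91 in FrD without low-complexity libraries, -0.86 (without mouse 9) to 0.91 (without mouse 3) in FrD with a mouse left out, 0.86 in FrD and 0.71 in FrE with voom, and 0.13 in FrD with the second-index covariate. In the WT steps it was 0.27 from FrB to FrC and -0.63 from FrC to FrD under ERCC scaling, and -0.13 from FrC to FrD without low-complexity libraries. With a mouse left out it ranged from -0.14 (mouse 3) to 1.75 (mouse 6) in that step and from -0.97 (mouse 7) to 2.18 (mouse 3) from FrD to FrE, which was -0.32 with voom. Its difference of steps was 1.06 from FrB to FrC without low-complexity libraries and ranged from -2.45 (mouse 3) to 0.75 (mouse 7) from FrD to FrE with a mouse left out. Under ERCC scaling, where the median of all genes from FrC to FrD moved to -2.39, that step was -0.54 for Cd79b, -1.13 for Xrcc6, -1.51 for Myb, -0.15 for Sox4, -0.90 for Fcmr, -0.97 for Blnk, -0.20 for Foxo1 and -0.57 for Rrm2b. The difference for Cmip from FrC to FrD was 0.13 with voom and 0.50 without low-complexity libraries. Without those libraries the erythroid list in FrB (adjusted p = 0.908) and the pre-B transcription factors in FrC (adjusted p = 0.424) changed sides.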

Other observations

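The test on shared indices, the position between fractions and the fits without low-complexity libraries were chosen only after the results were seen. Mutant FrE libraries lay between WT FrD and WT FrE in the genes that change between those stages. On the 608 genes called in that WT step, with the mean of WT FrD at 0 and of WT FrE at 1, the 5 mutant FrE libraries stood at 0.52 ± 0.07 (SD, range 0.44 to 0.63) and the 5 WT FrE libraries between 0.86 and 1.17. Genes rising in the step gave 0.51 ± 0.07 and falling genes 0.55 ± 0.18 (SD, n = 5). Mutant FrD libraries stood at 0.28 ± 0.07 on the same scale. The genes and the scale come from the same WT libraries, which places WT FrD near 0 and WT FrE near 1. It pulls any other FrD group above 0 and any other FrE group below 1, so no test of the genotype is given for either fraction. Without low-complexity libraries the mutant FrE mean was 0.50.

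Without the low-complexity libraries more genes were called in the later fractions. These genes were chosen for naming after their values were seen. In FrD, 11 genes were higher and 28 lower, with Tnfrsf13c at -2.60, the lymphotoxin gene Ltb at -2.27, the pre-B receptor adaptor Blnk at -1.46 and the B cell receptor chain Cd79a at -1.28, and the chaperone Sdf2l1 at 1.45, the seryl-tRNA synthetase gene Sars at 2.51 and the replication gene Mcm3 at 1.29. The granulocyte receptor gene Csf3r was among the higher ones at 8.08, and the granulocyte genes Mpo (7.88), Prtn3 (8.00), Ltf (7.51) and Mmp8 (6.50) were higher there without being called. In FrE, 16 were higher and 12 lower, with Cd74 at -1.88, Ms4a1 at -1.78 and Tnfrsf13c at -1.74, and Rag2 at 4.59, Il7r at 2.94, Cox6a2 at 2.88, Bach2 at 2.22, Ddit3 at 1.93 and Myb at 1.47.

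The FrE library of mutant mouse 9 held 42111 endogenous counts. Reads misassigned from libraries that share an index may make up most of it: when its profile was fitted as a mixture of the other 39, the 11 libraries that share 1 of its indices took 96.9% of the weight, where equal weights would give 28.2%. The same fit in the other 39 libraries gave a median of 48.2%, a 95th percentile of 75.2% and a highest value of 89.5%. Libraries of its own group without a shared index took 0.2%. Low input in the well remains open beside it and was not tested.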
